A study of Mus musculus with 23 samples.

How the data were processed

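Microglia were sorted by flow cytometry from the spinal dorsal horn of mice that carry a Venus reporter for CD11c, the protein encoded by Itgax, according to the study's design text. The sample labels give the tissue as brain and the genotype as wild type, which differs from that design text; the design text is followed for the tissue. The injury was a cut of a spinal nerve. CD11c-negative cells were taken without injury (day 0) and at 14 and 35 days after it, and CD11c-positive cells at 14 and 35 days. The labels do not say whether the replicates of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

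Libraries were made with CEL-Seq2, a method that tags the 3′ end of transcripts and amplifies them, per the labels' protocols. The reads were trimmed with Trim Galore, aligned with HISAT2 and counted with featureCounts on the mouse build GRCm38, per the submitters' processing notes. The versions of these tools, the strand setting and any use of molecular identifiers are not given in the sources used here. The deposited values are raw whole-number counts per gene and library, with no normalization, and are used as the authors deposited them. Without known identifiers a count may be a copy and not a separate molecule, so floors set from counts cover counting error only. Where the strand setting is unknown, overlapping and antisense genes cannot be told apart, and counts of near-identical genes (the H2 genes, Ifi204 and Ifi207, Ccl3 and Ccl4, Bcl2a1a) are uncertain.

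The table held 54100 gene identifiers, of which 20649 had a count in any library. All 54100 matched the GENCODE annotation of GRCm38, which supplied gene symbols and coordinates. Each of the 23 columns matched 1 sample by name. Total counts per library ran from 790655 to 1307658. A count of 3 over a whole group, the floor used for groups at 0, corresponds to between 0.557 and 0.847 CPM (counts scaled to a common library size).

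Genes were kept with the filterByExpr function of edgeR 4.0.16 at its minimum count of 10, by group, which left 8644 genes with 98.8% of the counts. Libraries were scaled with TMM factors. Counts of all 23 libraries were fitted with 1 mean for each of the 5 groups by edgeR's robust quasi-likelihood method in R 4.3.3, so that the groups share 1 estimate of the spread. A total of 7 contrasts were tested: each time against another in CD11c-negative cells, positive against negative cells at each time, the later against the earlier time in positive cells, and the difference between times of the positive-against-negative change (the interaction). Every p-value given as adjusted for a gene is from this edgeR test with Benjamini-Hochberg adjustment over the genes of that contrast, and a gene is called changed at an adjusted p under 0.05. Log2 fold changes are given with their standard error, and levels as mean CPM on TMM-scaled library sizes with the SD between libraries.

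A set of 27 gene lists was fixed before the data were examined, covering microglial states, pathways and markers of other cell types. Lists with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a contrast. The same test with a correlation estimated per list was run beside it. A total of 17 lists had enough members. Some lists share genes: the disease-associated list shares 6 genes with the lysosome list and 4 with the lipid list, and the homeostatic list shares 6 with the pain-linked list. The rule for named genes was also fixed beforehand. It takes a panel of 18 core genes, the 6 largest called changes in each direction at a mean of at least 30 CPM without predicted gene models, and up to 4 members with the smallest p of each list that passed camera or had at least 3 called members. Of these, the text prints the members that carry each comparison, and any gene outside the rule is said to be chosen after its values were seen.

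Alternatives fixed beforehand were RLE scaling, DESeq2 1.42.0, no filter, a filter of 30 CPM in 4 libraries, only the groups compared in the fit, limma voom with sample weights, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.01, and a minimum fold of 2. Scaling by total counts was chosen after seeing the data, because the TMM factors of the day 0 libraries (1.08 to 1.15) lay above most of the others (0.918 to 1.08). It shifts the median log2 change of all genes by -0.15 for day 14 and -0.12 for day 35 CD11c-negative cells against day 0, and by -0.11 for positive against negative cells at day 35. Directions given here are relative to TMM.

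The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For day 14 against day 0 CD11c-negative cells, over 8382 simulated genes, the test recovered 26 of the 2-fold and 73 of the 4-fold changes. Of the 17 genes changed 2-fold at over 100 CPM it recovered 15, and it called 0 unchanged genes. For positive against negative cells at day 35, over 8337 genes, it recovered 29 and 68, with 3 unchanged genes called. For positive cells at day 35 against day 14, over 8365 genes, it recovered 26 and 69, with 6 unchanged genes called. A 2-fold change in a gene with few counts was therefore often missed at this depth.

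Over the 42 pairs of libraries within a group, the chi-square statistic per degree of freedom ran from 3.93 to 12.2. Copies of molecules also raise this value, so it does not show that libraries came from separate animals, and each library was treated as 1 replicate as the labels name it. The highest value lay between day 35 negative replicates 1 and 5. The libraries of that group also had the lowest voom sample weights (0.741 to 0.904). The shared estimate of the spread may therefore be too small for contrasts with day 35 negative cells.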

Results

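Messenger RNA was counted in 23 libraries of sorted mouse spinal dorsal horn microglia, the resident macrophages of the central nervous system. There were 5 libraries of CD11c-negative cells from uninjured mice (day 0), 4 of CD11c-negative cells at day 14 after nerve injury and 5 at day 35, and 5 of CD11c-positive cells at day 14 and 4 at day 35. The total count per library ran from 790655 to 1307658, and between 11389 and 12242 genes had at least 1 count.

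Itgax, the gene of the CD11c protein used for the sort (chromosome 7, 128129547 to 128150657, plus strand, GRCm38), checks the labels. It lay between 142 and 317 CPM in the day 14 positive libraries and between 99.3 and 185 CPM in the day 35 positive libraries. In the negative libraries it lay between 0 and 9.32 CPM at day 0, between 28.4 and 69.5 CPM at day 14 and between 12.2 and 35.9 CPM at day 35. All positive libraries were above all negative libraries, and since this gene follows the sort, its difference between the gates is not a finding.

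The first principal component of the log2 CPM values held 16.2% of the variance and ordered the groups. The mean position was -31.0 ± 3.02 (SD, n = 5) for day 0, -19.4 ± 3.61 (n = 5) for day 35 negative cells, 1.50 ± 6.06 (n = 4) for day 14 negative cells, 25.9 ± 7.08 (n = 5) for day 14 positive cells and 29.1 ± 3.09 (n = 4) for day 35 positive cells.

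**Figure D1:**
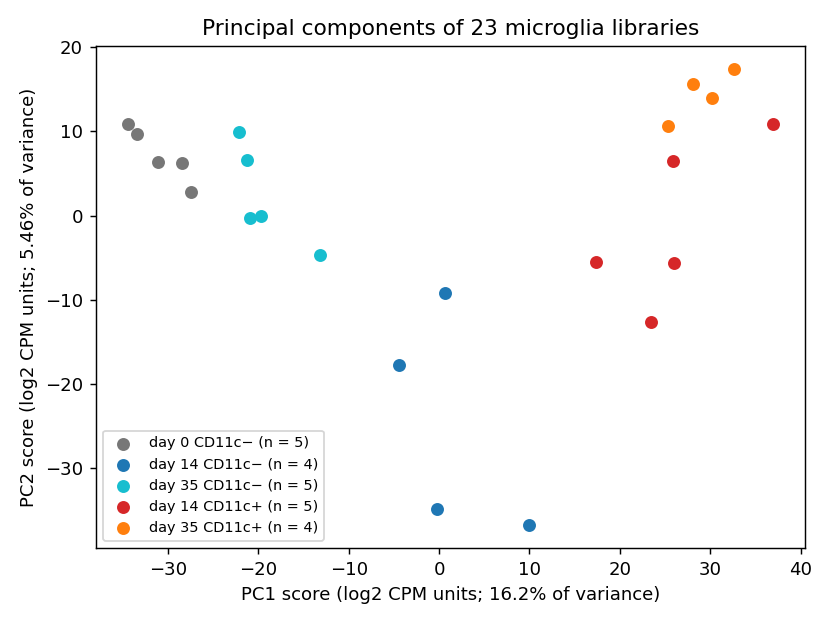
Position of the 23 libraries on the first and second principal component (score in log2 CPM units) of log2 CPM, 1 point per library, coloured by group. The first component holds 16.2% of the variance and runs from the day 0 libraries to the CD11c-positive libraries.

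Among the core genes are Apoe (chromosome 7, 19696109 to 19699188, minus strand), Clec7a (chromosome 6, 129461591 to 129472779, minus), Axl (chromosome 7, 25757273 to 25788705, minus), Spp1 (chromosome 5, 104435118 to 104441050, plus), Lpl (chromosome 8, 68880491 to 68907448, plus), Igf1 (chromosome 10, 87858265 to 87937042, plus), Il1b (chromosome 2, 129364570 to 129371139, minus), P2ry12 (chromosome 3, 59216272 to 59262871, minus), Tmem119 (chromosome 5, 113793729 to 113800516, minus) and Cx3cr1 (chromosome 9, 119901616 to 120069879, minus), all on GRCm38. The 3′ tags count whole genes, so no exon or isoform is resolved. Of the other core genes, Gpnmb had 79 counts in 7 libraries and Bdnf had 0 counts in all 23 libraries, and neither could be tested.

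The first comparison asked what differed in CD11c-negative microglia at day 14 after injury (n = 4) from day 0 (n = 5). Apoe, which encodes a lipid carrier protein, rose 37.2-fold, from 225 ± 104 to 8397 ± 943 CPM (log2 fold change 5.22 ± 0.34, adjusted p = 8.34e-09). Clec7a, a receptor for fungal glucans, rose 11.5-fold, from 58.3 ± 27.6 to 678 ± 75.3 CPM, and Axl, a receptor tyrosine kinase used in the uptake of dying cells, rose 11.7-fold. Chst2, a sulfotransferase, rose 23.4-fold and the chemokine receptor gene Cxcr4 16.2-fold (log2 fold change 4.02, and 5.34 without day 0 replicate 3). P2ry12, the ADP receptor that guides microglial processes, fell from 3721 ± 186 to 2483 ± 193 CPM (1.50-fold lower, adjusted p = 7.91e-05). In all, 374 genes changed, 296 higher and 78 lower. CD11c-positive cells that passed into the negative gate could also raise genes in this comparison. For Apoe, Axl, Lyz2 and Il1b, among others, even such cells at the mean Itgax level of the positive libraries could not be told apart from a change in the negative cells.

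Of the 36 tested genes of the disease-associated microglia list, 23 rose and 0 fell (26 and 0 adjusted over the list alone). Cd63, a membrane protein of late endosomes and lysosomes, rose 3.45-fold from 414 ± 50.9 to 1431 ± 46.6 CPM, and Lyz2, which encodes lysozyme, rose 3.75-fold. Of 50 lysosome and phagocytosis genes, 23 rose and 0 fell (28 and 0 adjusted over the list alone), among them the cathepsin protease genes Ctsb (2.12-fold), Ctsl (1.85-fold) and Ctss (1.55-fold). Of 15 genes of lipid handling, 5 rose (6 adjusted over the list alone), including the cholesterol exporter genes Abca1 (2.07-fold) and Abcg1 (2.22-fold). The interferon list had 17 of 38 genes higher and 0 lower (26 and 0 adjusted over the list alone). Ifi204 rose 7.18-fold, Ifitm3, an antiviral membrane protein gene, 7.82-fold and Lgals3bp 4.63-fold. Of 21 antigen presentation genes, 4 rose (8 adjusted over the list alone), among them the class I heavy chain genes H2-D1 (2.73-fold) and H2-K1 (2.02-fold) and their light chain B2m (2.12-fold). All 5 of these lists passed camera upwards, also with an estimated correlation.

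Of 30 cytokine and chemokine genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone). Il1b, the gene of the inflammatory cytokine interleukin-1 beta, rose 2.67-fold from 570 ± 203 to 1521 ± 137 CPM. Ptgs2, a prostaglandin synthase, rose 3.06-fold and Ccl3 1.76-fold. Ribosomal protein genes rose in 63 of 79 cases and fell in 0 (73 and 0 adjusted over the list alone). Their share of all counts was 2.39 ± 0.0854% at day 0 and 3.37 ± 0.135% at day 14, while the mitochondrial share was 12 ± 1.54% and 14.9 ± 1.54%. Of 68 genes of oxidative phosphorylation, 5 rose (6 adjusted over the list alone), including the complex III genes Uqcrh (1.86-fold) and Uqcrq (1.96-fold). These 3 lists passed camera with both correlations.

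The homeostatic list had 9 of 35 genes lower and 1 higher (13 and 1 adjusted over the list alone) and passed camera downwards with both correlations. P2ry13, another ADP receptor gene, was 1.76-fold lower, the fructose transporter gene Slc2a5 2.05-fold lower and Sall1, a transcription factor of microglial identity, 1.45-fold lower. Bank1, a signalling scaffold of B cells, was 4.34-fold lower and Idh2, the mitochondrial isocitrate dehydrogenase, 3.25-fold lower. Tmem119 (adjusted p = 0.573), Csf1r (0.992), Spp1 (0.0605), Lpl (0.197) and Igf1 (0.541) did not pass. Pain-linked genes (7 higher and 3 lower of 32, 8 and 3 adjusted over the list alone), glycolysis genes (2 higher of 18, 4 higher and 1 lower alone) and mitochondrially encoded genes (4 higher of 9, 7 alone) passed camera upwards, but each had an adjusted p = 0.0991 with an estimated correlation, and the median of the pain-linked list turns negative with total-count scaling. Cholesterol synthesis passed downwards with 0 of 16 genes called (adjusted p = 0.148 with an estimated correlation and 0.0706 with the replicate block). Total-count scaling called 169 genes higher and 154 lower, and leaving out day 14 negative replicate 2 left 227 genes.

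**Figure D2:**
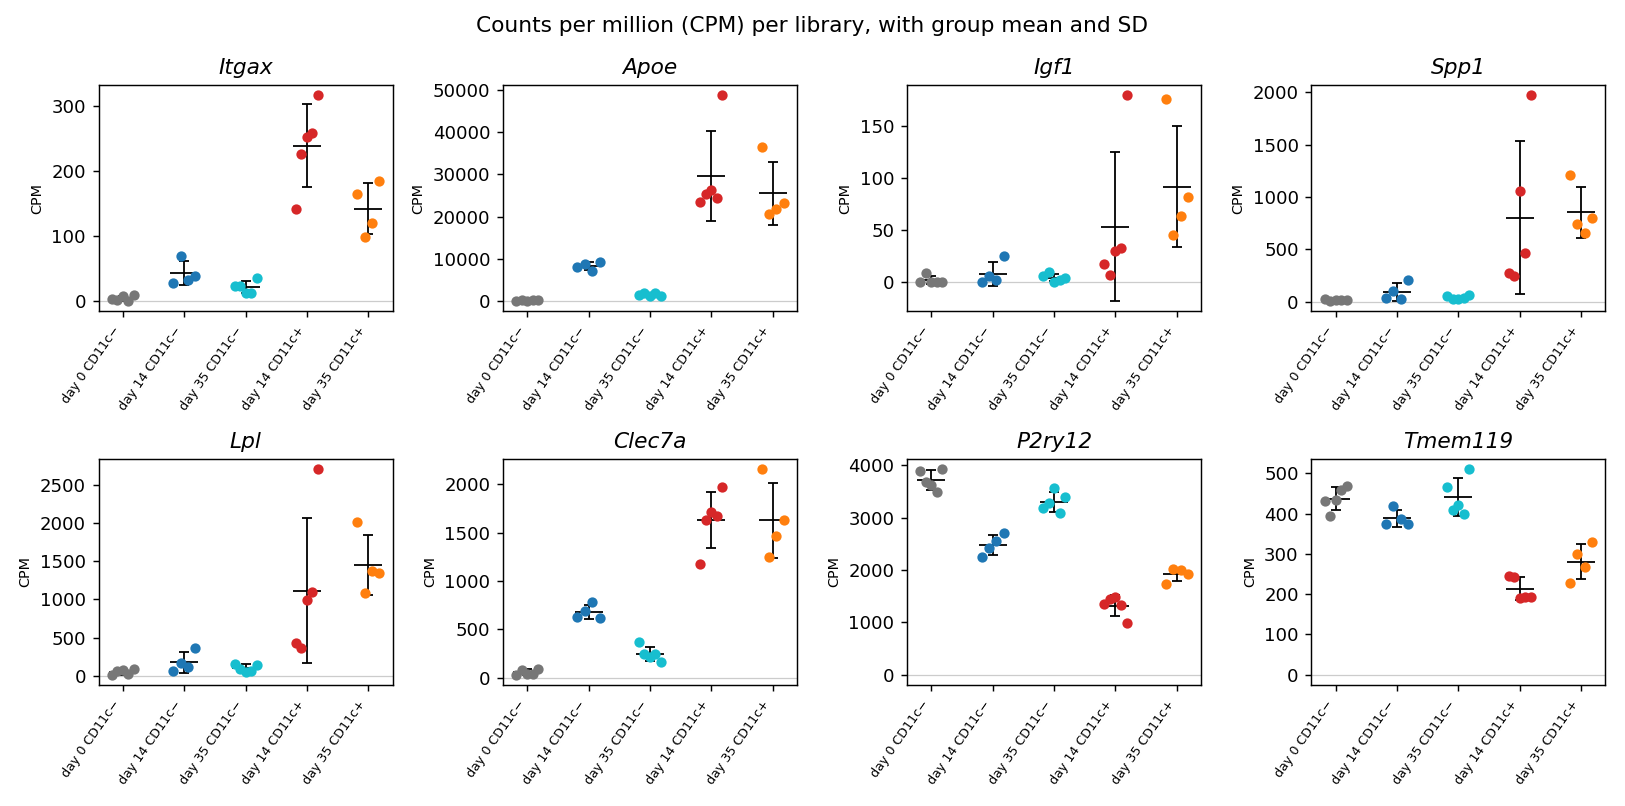
CPM (linear axis) of 8 core genes in each library, 1 point per library in 5 groups, with the group mean as a horizontal line and the SD as error bars. Apoe has a mean of 225 CPM at day 0 and 8397 CPM in day 14 CD11c-negative cells, and P2ry12 has means of 3721 and 2483 CPM in the same groups.

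The second comparison set CD11c-negative cells at day 35 (n = 5) against day 0 (n = 5). Apoe was 7.05-fold higher, at 1592 ± 346 CPM (log2 fold change 2.82 ± 0.31, adjusted p = 6.73e-05), and Clec7a 4.21-fold higher, at 248 ± 74.1 CPM. Lyz2 was 2.22-fold and Cd63 1.64-fold higher. Fgl2, which encodes a fibrinogen-like secreted protein, was 3.26-fold higher and Sorl1, a sorting receptor gene, 2.81-fold. In all, 50 genes changed, 46 higher and 4 lower. The 4 lower genes include Hpgd, which degrades prostaglandins, at 1.34-fold lower (adjusted p = 0.0458, up to 0.178 without 1 of day 0 replicates 2, 3 and 5 or day 35 negative replicates 2, 3 and 4, and up to 0.0937 with no filter, the replicate block or only these groups fitted). The other 3, named after their values were seen, are 2310061I04Rik (3.58-fold lower), 2610301B20Rik (4.64-fold lower) and Cd300lb, which had 0 counts in all 5 day 35 negative libraries and 6.09 ± 5.86 CPM at day 0.

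Of the 36 disease-associated genes, 11 were higher and 1 lower (16 and 1 adjusted over the list alone), and 2 of 15 lipid handling genes were higher (5 alone). Ribosomal protein genes were higher in 15 of 79 cases (67 adjusted over the list alone), such as Rpl23 by 1.56-fold, and mitochondrially encoded genes in 7 of 9 (8 alone), such as mt-Cytb by 1.43-fold. The mitochondrial share of counts was 16.8 ± 3.33% at day 35, with 21.4% in replicate 1, against 12 ± 1.54% at day 0. These 4 lists and antigen presentation (0 of 21, 2 alone) passed camera upwards with both correlations. The homeostatic list, with 0 of 35 called (0 higher and 1 lower alone), passed camera downwards (adjusted p = 0.184 with an estimated correlation), and P2ry12 was not called (adjusted p = 0.618). The lysosome list (4 of 50 higher, 4 alone, adjusted p = 0.132 with an estimated correlation) has a median log2 change of 0.11 that turns to -0.01 with total-count scaling. The interferon (adjusted p = 0.280), glycolysis (0.157), oxidative phosphorylation (0.0953), cell cycle (0.0752) and immediate-early (0.521) lists also lost their calls with an estimated correlation. Only 23 genes were called with total-count scaling, 17 higher and 6 lower, and 74 without day 35 negative replicate 1. The count was 23 without day 0 replicate 4, and 28 and 30 without day 35 negative replicates 2 and 3.

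The 2 injury comparisons share their day 0 libraries. Of the 46 genes higher at day 35, 39 were also higher at day 14, where independent lists would share 1.58. Simulated unchanged groups against the same controls shared 0 in 20 simulations, where groups without an effect give few calls to share. With the controls split, 4 genes were shared between lists of 65 and 6 (0.0528 by independence), and the other split, with lists of 181 and 0, cannot show an overlap.

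The third comparison, day 35 (n = 5) against day 14 (n = 4) in CD11c-negative cells, gave 74 changed genes, 16 higher and 58 lower. Apoe was 5.27-fold lower (log2 fold change -2.40 ± 0.30, adjusted p = 0.000266) and Clec7a 2.73-fold lower. Cd63 was 2.11-fold lower, from 1431 ± 46.6 to 678 ± 26.9 CPM, Ctsb 1.63-fold lower and Abca1 1.67-fold lower. Il1b was 2.07-fold lower and Ptgs2 2.04-fold lower. Among interferon genes, Ifi207 was 7.44-fold, Ifitm3 5.30-fold and Ifi204 2.54-fold lower. P2ry13 was 1.62-fold higher (adjusted p = 2.20e-05) and E2f3, a transcription factor of the cell cycle, 4.20-fold higher.

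Of 36 disease-associated genes, 15 were lower and 0 higher (22 and 0 adjusted over the list alone), and the counts were 9 of 50 for lysosome (26 alone), 8 of 38 for interferon (21 alone), 3 of 15 for lipid handling (4 alone), 3 of 21 for antigen presentation (3 alone) and 5 of 30 for cytokines and chemokines (10 alone), with 0 higher. The 3 antigen presentation genes, B2m, H2-K1 and H2-D1, all lost their calls without day 14 negative replicate 2 and also without replicate 3 (adjusted p up to 0.328). The homeostatic list had 2 of 35 genes higher and 0 lower (8 and 1 adjusted over the list alone). These lists passed camera with both correlations. The pain-linked (adjusted p = 0.125), trophic factor (0.0591), cell cycle (0.0710), oxidative phosphorylation (0.110) and ribosomal (0.20) lists passed downwards but not with an estimated correlation. P2ry12, 1.33-fold higher, lost its call without day 14 negative replicates 1 or 2 or day 35 negative replicate 3 (adjusted p up to 0.0783). The count was 35, 40 and 48 without day 14 negative replicates 2 and 3 and day 35 negative replicate 5.

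The fourth comparison set CD11c-positive (n = 5) against CD11c-negative cells (n = 4) at day 14. Apoe was 3.53-fold higher in positive cells, at 29652 ± 10694 against 8397 ± 943 CPM (log2 fold change 1.82 ± 0.31, adjusted p = 0.00305). Olr1, a receptor for oxidised lipoproteins, was 8.88-fold higher (log2 fold change 3.15, and 4.02 without day 14 negative replicate 4) and Lgals3, which encodes galectin-3, 7.97-fold. Cd14, a co-receptor for bacterial lipopolysaccharide, was at 3745 ± 286 against 1710 ± 324 CPM (2.19-fold, adjusted p = 6.2e-08), and Il1b was 2.27-fold higher. P2ry12 was 1.88-fold lower in positive cells, Tmem119, a microglial surface marker, 1.82-fold lower and Cx3cr1, the fractalkine receptor gene, 1.42-fold lower. In all, 130 genes changed, 71 higher and 59 lower.

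Of 36 disease-associated genes, of which Itgax is one and was used for the sort, 19 were higher and 0 lower (28 and 0 adjusted over the list alone). Clec7a was 2.41-fold, Lyz2 2.15-fold, Cd63 1.73-fold and Ank, a phosphate transporter gene, 3.45-fold higher. Of 15 lipid handling genes, 6 were higher (10 alone), among them Scd2, a fatty acid desaturase gene, by 3.36-fold. Of 35 homeostatic genes, 13 were lower and 0 higher (21 and 0 adjusted over the list alone), among them Selplg by 1.54-fold. Cytokine and chemokine genes had 3 of 30 higher and 1 lower (13 and 2 alone), the lower one being Nfkbia, an inhibitor of NF-kappa-B, by 1.43-fold. Glycolysis (1 of 18 higher, 5 alone) and trophic factors (1 of 18 higher, 1 alone) passed camera upwards, as did the lists above in their directions, with both correlations. The lysosome list (4 higher and 1 lower of 50, 9 and 4 alone) passed upwards (adjusted p = 0.341 with an estimated correlation). Ctsb was 1.38-fold higher and Lgmn, also a lysosomal protease gene, 1.29-fold lower. The immediate-early list had 0 of 34 higher and 4 lower (0 and 9 alone), including Jun by 1.59-fold (adjusted p = 0.310 with an estimated correlation). The interferon list passed downwards with 1 of 38 genes lower (1 alone), Gbp7, whose call was lost without day 14 negative replicate 1 (adjusted p = 0.0877, and adjusted p = 0.166 for the list with an estimated correlation). Mitochondrially encoded genes passed upwards with 0 of 9 (1 alone, adjusted p = 0.489 with an estimated correlation).

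Spp1, which encodes osteopontin, was 8.45-fold higher (804 ± 731 against 94.6 ± 84.4 CPM, adjusted p = 0.0145) and Lpl, lipoprotein lipase, 6.37-fold higher (adjusted p = 0.0438). Their log2 fold changes of 3.08 and 2.67 were 2.43 and 2.04 without positive replicate 5, and 3.83 and 3.33 without day 14 negative replicate 4. Spp1 lost its call without day 14 negative replicates 1 or 3 (adjusted p up to 0.0703) and with the replicate block or only these groups fitted (up to 0.238), and Lpl without day 14 negative replicates 1, 2 or 3 or positive replicates 3, 4 or 5 (up to 0.150) and with no filter, the replicate block or only these groups fitted (up to 0.238). Igf1 was at 53.2 ± 71.6 against 7.87 ± 11.4 CPM and did not pass (adjusted p = 0.287), with 180 CPM in positive replicate 5. Without day 14 negative replicate 4 the count of changed genes was 75.

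The fifth comparison, CD11c-positive (n = 4) against CD11c-negative cells (n = 5) at day 35, called 550 genes, 354 higher and 196 lower. Apoe was 16-fold higher in positive cells, at 25529 ± 7411 against 1592 ± 346 CPM (log2 fold change 4.00 ± 0.32, adjusted p = 1.28e-07). Spp1 was 21.0-fold higher (853 ± 243 against 40.5 ± 17.5 CPM), Lpl 14.7-fold and Igf1, insulin-like growth factor 1, 21.8-fold (91.7 ± 58.6 against 4.10 ± 3.56 CPM, adjusted p = 0.0107). Lgals3 was 45.5-fold higher (log2 fold change 5.51, and 6.13 without day 35 negative replicate 2). Fn1 (fibronectin), Mmp12 (a matrix metalloprotease) and Cd300lb (a myeloid receptor) had 0 counts in all day 35 negative libraries. Their means in positive cells were 148-fold, 77.3-fold and 72.9-fold above a floor of 3 counts over the negative group. These ratios leave out the error of the positive mean and take each count as a separate molecule, so they are not strict minima. The fitted log2 fold change of Mmp12, 8.44, was 7.58 without day 35 positive replicate 2.

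Of 36 disease-associated genes, Itgax among them, 31 were higher and 0 lower (35 and 0 adjusted over the list alone), including Clec7a by 6.56-fold, Axl by 5.85-fold and Cybb, a subunit of the phagocyte NADPH oxidase, by 14-fold. Of 50 lysosome genes, 22 were higher and 0 lower (28 and 4 alone), including Atp6v1a, a proton pump subunit, by 2.42-fold, and Cd63 by 3.45-fold. Of 15 lipid handling genes, 11 were higher (12 alone). Cytokine and chemokine genes had 17 of 30 higher and 0 lower (19 and 2 alone): Il1b was 4.99-fold higher (3667 ± 339 against 735 ± 90.2 CPM), Ptgs2 3.62-fold and Cxcl2 2.62-fold. Glycolysis had 8 of 18 higher (9 alone), with the glucose transporter gene Slc2a1 3.43-fold and Pkm 2.07-fold higher. Oxidative phosphorylation had 4 of 68 higher (9 alone), trophic factors 4 of 18 higher (6 higher and 1 lower alone) and cell cycle 2 of 15 (6 and 1 alone). The cell cycle genes were Tubb5, a tubulin, at 1.42-fold higher, and Top2a, a topoisomerase (adjusted p = 0.0479), which lost its call without any 1 of 6 libraries (up to 0.264) and with total-count scaling, the replicate block or voom (up to 0.385). The pain-linked list had 7 of 32 higher and 3 lower (10 and 6 alone), with Cd14 3.81-fold higher. P2rx4, an ATP-gated channel studied in neuropathic pain, was 1.72-fold higher (adjusted p = 0.0169) and lost its call without day 35 positive replicate 2 (0.0734).

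Of 35 homeostatic genes, 18 were lower and 0 higher (26 and 1 adjusted over the list alone), including P2ry12 by 1.72-fold, Sall1 by 1.72-fold, Tmem119 by 1.57-fold and Nav3 by 2.15-fold. These 10 lists passed camera with both correlations, the homeostatic list downwards and the others upwards. Ribosomal protein genes (21 of 79 higher, 44 higher and 1 lower alone, adjusted p = 0.0546 with an estimated correlation), mitochondrially encoded genes (3 of 9 higher, 5 alone, adjusted p = 0.180), antigen presentation (1 of 21, H2-K1, whose call was lost without any 1 of 8 libraries, 3 alone, adjusted p = 0.120) and cholesterol synthesis (1 of 16, 3 alone, adjusted p = 0.169) passed upwards but not with an estimated correlation. The interferon list did not pass, with 3 of 38 genes higher and 3 lower (4 and 3 alone), among them Cxcl10 at 2.57-fold higher and Herc6 at 3.48-fold lower, and its median changes sign with total-count scaling. The immediate-early list did not pass either, with 1 of 34 genes higher and 4 lower (4 and 7 alone), among them Jun at 1.54-fold and Egr1 at 1.53-fold lower. Total-count scaling called 243 genes higher and 339 lower.

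**Figure D3:**
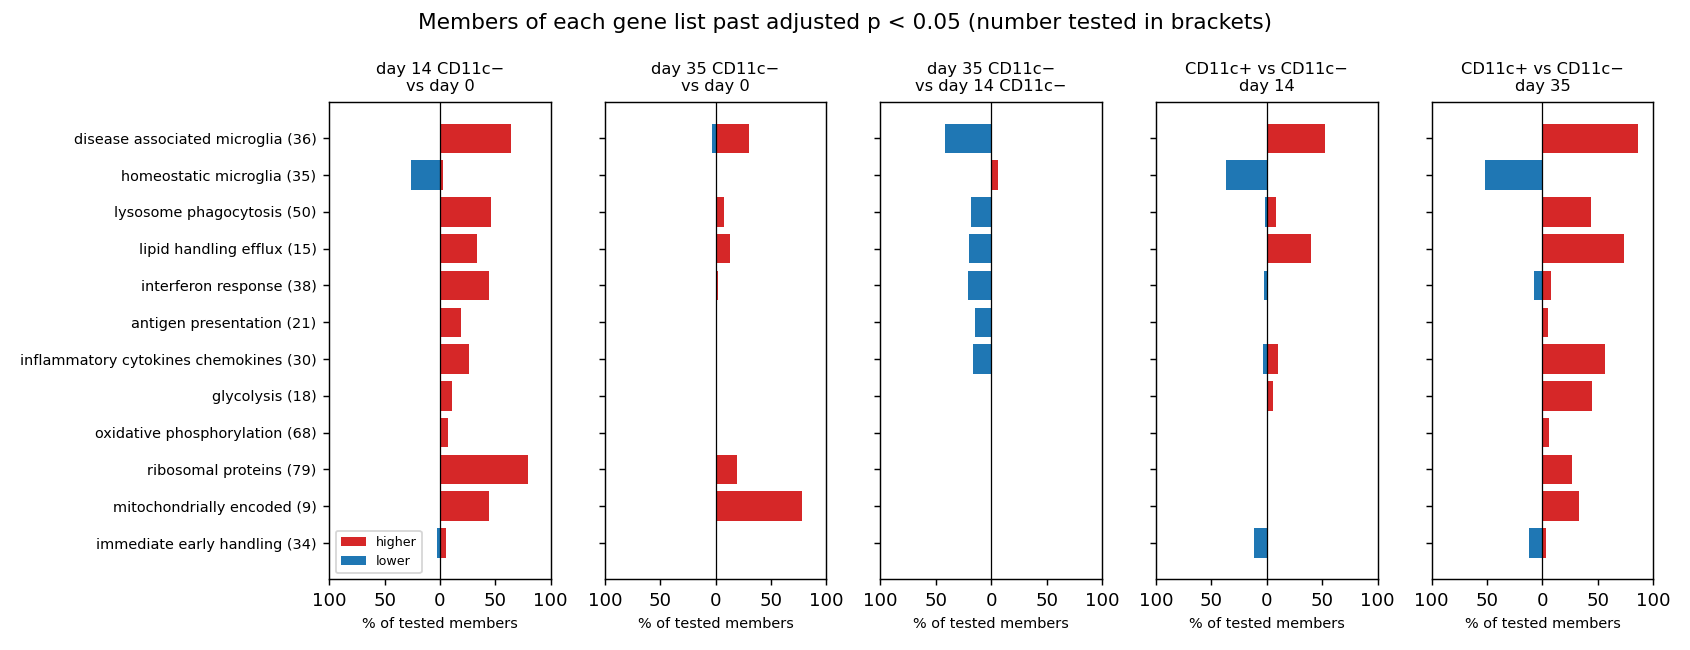
Percent of the tested members of each gene list called higher (red bars, to the right) or lower (blue bars, to the left) at an adjusted p under 0.05 in 5 contrasts, with the number tested in brackets. The disease-associated list has 31 of 36 members higher and 0 lower in day 35 CD11c-positive against negative cells.

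The calls of both positive-against-negative comparisons overlapped. A total of 58 genes were higher and 39 lower in both, where independent lists would share 2.91 and 1.34, and 0 genes were called in opposite directions.

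The sixth comparison, CD11c-positive cells at day 35 (n = 4) against day 14 (n = 5), called 6 genes. P2ry13 was 1.59-fold higher at day 35 (log2 fold change 0.67 ± 0.09, adjusted p = 9.15e-05) and P2ry12 1.45-fold higher (adjusted p = 0.00345, and 0.0511 with only these groups fitted). Hspa5, an endoplasmic reticulum chaperone gene, was 1.64-fold lower (2906 ± 128 to 1769 ± 214 CPM) and Abca1 1.45-fold lower. Cx3cr1 was 1.33-fold higher, and lost its call without day 35 positive replicates 2, 3 or 4 (adjusted p up to 0.113) and with total-count scaling or only these groups fitted (up to 0.0633). Ppp1r9a, a scaffold of the actin cytoskeleton, was 2.01-fold lower, and lost its call without day 14 positive replicates 3 or 4 or any of the 4 day 35 positive replicates (up to 0.170) and with no filter, the replicate block or only these groups fitted (up to 0.131).

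Of 36 disease-associated genes 0 were called at either adjustment, and the adjusted p of Igf1 was 0.939. The count at an unadjusted p under 0.05 over all genes was 601, and DESeq2 called 28 genes. The homeostatic list had 3 of 35 higher (8 alone) and passed camera upwards (adjusted p = 0.0670 with an estimated correlation). The interferon list passed downwards and cholesterol synthesis upwards (adjusted p = 0.0670 for each with an estimated correlation), and the pain-linked (adjusted p = 0.219), ribosomal (0.488) and mitochondrially encoded (0.219) lists upwards.

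The last comparison asked whether the difference between positive and negative cells differed between day 35 and day 14, and called 5 genes. The difference was larger at day 35 for Cd63 by 0.99 ± 0.16 on the log2 scale (adjusted p = 0.00227), for Il1b by 1.14 ± 0.22 (0.0375), for Bcl2a1a, an inhibitor of cell death, by 1.09 ± 0.21 (0.0321) and for Cd14 by 0.80 ± 0.16 (0.0371), and smaller for Magef1 (-2.25 ± 0.47, 0.0490). Cd63 kept its call without any of the 18 libraries, and the others lost theirs without 10 to 14 of them (adjusted p up to 0.146). The replicate block ended the calls of Il1b and Magef1 (0.0570 for each), voom and a fit of only these groups that of Magef1 (up to 0.131), and total-count scaling that of Cd14 (0.0537). The number of genes called ran from 1 to 10 when 1 library was left out. Of 36 disease-associated genes 1 was called (16 alone), of 50 lysosome genes 1 (8 alone), of 30 cytokine and chemokine genes 1 (2 alone) and of 32 pain-linked genes 2 (2 alone), with 0 smaller. These 4 lists passed camera upwards with both correlations. Apoe (2.18 ± 0.42, adjusted p = 0.0648) did not pass. The lipid handling (adjusted p = 0.271), interferon (0.0943), cell cycle (0.0887), oxidative phosphorylation (0.0799) and ribosomal (0.141) lists passed upwards but not with an estimated correlation.

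Markers of other cell types were measured beside these groups. The border macrophage list summed to 1156 ± 152 CPM at day 0, 933 ± 88.2 and 985 ± 114 CPM in negative cells at day 14 and day 35, and 640 ± 78.3 and 685 ± 85.2 CPM in positive cells, most of it Maf, a gene microglia also express. The dendritic cell list summed to 1562 ± 90.1 CPM at day 0 and 864 ± 76.5 CPM in day 14 positive cells, led by Siglech, which is also on the homeostatic list. Monocyte markers summed to 618 ± 128 CPM at day 0, 586 ± 24.3 and 542 ± 46.0 CPM in negative cells at day 14 and day 35, and 672 ± 99.7 and 677 ± 70.6 CPM in positive cells. Most of each sum was Nr4a1, at 596, 549, 531, 580 and 576 CPM in the same order, so the sums hide changes in the other members. Fn1 was at 0.928, 6.95, 0, 62.4 and 82.7 CPM in that order. Neutrophil markers, nearly all Csf3r, had means between 207 and 264 CPM, and T and NK cell markers, mostly Il7r, between 21.5 and 87.5 CPM. B cell markers, mostly Ighm, were at 229 ± 11.8 CPM at day 0 and 140 ± 14.6 CPM in day 14 positive cells. Neuron markers, mostly Rtn1, were at 151 ± 39.1 and 59.2 ± 19.1 CPM in the same groups. Astrocyte markers, led by Glul, had means between 822 and 1016 CPM, oligodendrocyte markers, led by Trf, between 484 and 585 CPM, endothelial and mural markers, led by Bsg, between 132 and 191 CPM, and erythroid markers at most 1.37 CPM. Of these lists only the oligodendrocyte list had enough tested members for camera, and it passed in 0 of the 7 contrasts. Named after their values were seen, Maf (adjusted p = 0.0111 at day 14 and 0.0035 at day 35), Siglech (0.000129 and 0.000634) and Rtn1 (0.0261 and 0.0245) were lower in positive than in negative cells, Flt1 was higher in positive cells at day 35 (0.0193) and Ighm was lower in day 14 negative cells than at day 0 (0.0172).

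The median, mean and test direction of a list differed in sign only in lists that did not pass camera. These were cell cycle at day 14 and the cytokine, trophic factor, pain-linked and oligodendrocyte lists at day 35 in negative cells against day 0, the oligodendrocyte list in positive against negative cells at day 35, the disease-associated and oligodendrocyte lists in positive cells between the times, and the homeostatic and cholesterol synthesis lists in the interaction.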

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

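The test of carry-over between the gates in the first pattern was chosen only after the result was seen.

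The difference between CD11c-positive and CD11c-negative cells was larger at day 35 than at day 14 for Cd63 (0.99 on the log2 scale), Il1b (1.14), Bcl2a1a (1.09) and Cd14 (0.80), and lower for Magef1 (-2.25), by the test of the interaction. A candidate explanation is that more CD11c-positive cells were carried over into the negative gate at day 14 than at day 35. If those cells held the mean Itgax level of the positive libraries, each gene would gain the same share of the day 14 positive-minus-day 35 negative difference as Itgax. Between the negative cells of both times that share was 9.71% (95% bootstrap interval 2.68 to 19.3). In libraries left out of the call the share of Cd63 was 41.5% (27.5 to 70.5 over the 92 of 100 fits that called it). This argues against carry-over of cells at that Itgax level as the whole cause for Cd63, but not against carry-over of cells with less Itgax. The share was 26.7% for Bcl2a1a (7.89 to 37.6, above Itgax in 32 of the 35 fits that called it) and 10.9% for Cd14 (-4.34 to 29.8, above in 20 of 34), and 0 fits called Il1b, so for these 3 genes carry-over and a change in the cells cannot be told apart, because the ranges reach into the interval of Itgax or hold no fit. Cd63 was called lower in negative cells at day 35 than at day 14, and was not among the 6 genes called between the times in positive cells. The larger difference therefore came with a fall in the negative cells, though a missing call does not show that the positive cells were unchanged. A change in the negative cells may explain Cd63 and stays a hypothesis, and a difference in RNA quality was not tested.

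Single libraries lay far from the others of their group in 6 of 100 values tested, where chance at 1 in 20 gives 5. Igf1 was at 180 CPM in day 14 positive replicate 5, with the others between 6.58 and 32.8 CPM. Apoe in the same library was at 48682 CPM, with the others between 23427 and 26308 CPM. Igf1 was at 8.06 CPM in day 0 replicate 2 and at 0 in the other 4 day 0 libraries. Day 14 negative replicate 1 had 11859 genes detected, with 11389 to 11465 in the others. Day 35 positive replicate 4 had a total of 929440 counts, with 1173379 to 1208587 in the others, and 11509 genes detected, with 11699 to 11737 in the others.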

How the results depend on the processing

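Total-count scaling was the alternative chosen only after the data were seen. Among values of named genes under other settings or with 1 library left out, 5168 kept their side of the threshold, 694 lost a call, 23 gained one and 0 changed direction. These are pairs of gene and setting and include uncalled genes, which have no call to lose. By gene, in the order of the 7 contrasts, 35 of 59, 16 of 21, 23 of 35, 27 of 41, 37 of 69, 6 of 6 and 5 of 5 called named genes lost their call in at least 1 other setting, the stricter thresholds included. With 1 library left out, 17, 6, 21, 19, 15, 2 and 4 of them did. With an adjusted p under 0.01 the number of changed genes was 198 for day 14 and 19 for day 35 negative cells against day 0, 34 between these times, 63 and 274 for positive against negative cells at day 14 and day 35, and 1 for the interaction. A minimum fold of 2 gave 116, 17, 33, 61, 241, 1 (positive cells between the times) and 3. These settings ask for more and so give fewer genes. For day 35 negative cells against day 0 (50 genes) the number was 23 with total-count scaling, 78 with no filter, 111 with DESeq2 and 22 with only these groups fitted. For day 35 against day 14 negative cells (74) it was 129 with no filter, 47 with voom, 134 with DESeq2 and 42 with only these groups. For positive cells between the times (6) it was 15 with no filter, 10 with the filter of 30 CPM, 11 with voom and 28 with DESeq2. For the interaction (5) it was 33 with no filter, 9 with voom and 28 with DESeq2. The cause of these differences was not tested. Leaving out 1 library gave 227 to 339, 23 to 74, 35 to 80, 75 to 130, 376 to 564, 4 to 9 and 1 to 10 genes for the 7 contrasts in the order of the report. The number of gene lists past camera with an estimated correlation was 9, 5, 7, 6, 10, 0 and 4, against 13, 12, 12, 10, 14, 6 and 9 with the preset one. At this depth, 26 of 100 simulated 2-fold changes were found for day 14 against day 0 negative cells, but 15 of 17 over 100 CPM.

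Replicate numbers are shared between groups, but the labels do not say that they mark the same animals. Over 2360 genes, deviations from the group mean were correlated between same-numbered libraries, and the values ran from -0.0689 to 0.167. The mean was highest between the gates at day 14 (0.0666, 2 of 4 libraries best with their own number). Between day 0 and day 14 negative cells, which cannot share animals, the mean was 0.0567 (3 of 4). Between the gates at day 35 it was -0.00144 (0 of 4). The interferon list summed to 2900, 2907, 3764 and 2210 CPM in day 14 negative replicates 1 to 4. In the positive ones it summed to 2434, 2454, 3332 and 2170 CPM, in the same order, but at day 35 the orders differed. For the antigen presentation list the orders differed at day 14. Replicates 1 and 4 were at 11157 and 10091 CPM in negative cells and at 12936 and 13284 CPM in positive cells. Shared animals at day 14 are possible, but these values are not evidence for them, and the pairing is not established. With the replicate block the numbers of changed genes were 362, 57, 64, 122, 596, 5 and 8. Among others, it ended the calls of Il1b and Magef1 among the 5 interaction genes (adjusted p = 0.0570 for each), of Hpgd in day 35 negative cells against day 0 and of Ppp1r9a in positive cells between the times. The block ended the camera call of cholesterol synthesis in day 14 negative cells (adjusted p = 0.0706) and gave 1 to ribosomal genes at day 14 in positive cells (0.0496) and to oxidative phosphorylation in positive cells between the times (0.0408).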

Other observations

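The tests of carry-over and of copied molecules were chosen only after the results were seen, and the tests on other splits of the libraries were planned.

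The interferon list had its highest mean in day 14 negative cells, at 5.70 ± 0.26 log2 CPM (SD, n = 4), against 4.33 ± 0.25 (n = 5) at day 0 and 4.56 ± 0.32 (n = 5) in day 35 negative cells. In positive cells it was 5.29 ± 0.24 (n = 5) at day 14 and 4.77 ± 0.34 (n = 4) at day 35. The glycolysis list ran from 4.93 ± 0.19 at day 0 through 5.19 ± 0.13 and 5.17 ± 0.14 in negative cells to 5.75 ± 0.23 and 5.90 ± 0.06 in positive cells at day 14 and day 35. The antigen presentation list was at 5.73 ± 0.36 at day 0 and 6.55 ± 0.17 and 6.71 ± 0.15 in day 14 negative and positive cells.

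Day 14 positive replicate 5 had the highest values of its group for Igf1 (180 CPM), Apoe (48682 CPM), Spp1 (1973 CPM) and Lpl (2709 CPM), and day 35 positive replicate 1 those of its own group for Igf1 (177 CPM), Apoe (36518 CPM), Spp1 (1208 CPM) and Lpl (2008 CPM). On the second principal component, day 14 negative replicates 2 and 3 lay at -36.8 and -34.9, and the other 2 at -17.7 and -9.20.

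The genes higher in day 14 negative cells than at day 0 could come from CD11c-positive cells carried over into the negative gate. If such cells held the mean Itgax level of the positive libraries, each gene would gain the same share of the positive-minus-day-0 difference as Itgax. That share was 16.3% (95% bootstrap interval 10.1 to 25.3). Over 295 genes the median share was 84.4% (66.0 to 101). In libraries left out of the call it was 66.2% (44.4 to 110 over 100 fits, which reuse the same libraries). Itgax had 14.2% (6.22 to 48.9) in those libraries, and the median lay above it in 100 of 100 fits. This argues against carry-over of cells at that Itgax level as the whole cause. Because the sort follows Itgax, cells that pass into the negative gate may hold less of it. A share above that of Itgax does not exclude carry-over of such cells. Added cells at the positive mean cannot lift a gene above that mean. Of the 296 genes called higher, 104 had a mean in day 14 negative cells at or above that in day 14 positive cells. Only 1 of the 296 was called lower in positive than in negative cells, so this excess was mostly not beyond the spread and does not decide the question. Of 294 genes other than Itgax, 83 were called in over 50% of these fits and lay above both the upper bound of Itgax and its value in the same libraries in each fit that called them, among them Clec7a (37.7%, 28.1 to 65.6), Cd63 (49.6%, 34.1 to 76.1), Ctsb (56.6%, 36.4 to 101), Abca1 (63.6%, 53.4 to 77.9) and Ifi204 (102%, 55.4 to 123). For the other 211, even carry-over of cells at the mean Itgax level cannot be told apart from a change in the negative cells. In some fit their share lay at or under the upper bound of Itgax or its value in the same libraries, or at most 50% of the fits called the gene. They include Apoe (32.3%, 14.2 to 39.9, above Itgax in 90 of 100 fits), Il1b (32.6%, 19.2 to 53.6, 93 fits), Lyz2 (38.1%, 25.1 to 63.5, 99 fits), Axl (33.6%, 12.7 to 65.0, 100 fits) and Cd14 (22.9%, 3.56 to 44.4, 76 fits). A change of the negative cells after injury stays a hypothesis, and a difference in RNA quality was not tested.

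Counts of sparsely counted genes varied more between libraries than single molecules would. Copies of 1 molecule counted as separate reads may explain this. Among 6175 gene and group pairs with a mean between 0.5 and 1 count, the median ratio of variance to mean was 2, and 60.3% of the counts above 0 exceeded 1. With a mean between 0.2 and 0.5 count (9507 pairs) the median ratio was 1 and 18.1% exceeded 1, but 6928 of these pairs hold 1 count in total, which fixes the ratio at 1, and of 4210 pairs with a total of 2 counts 72.7% (71.4 to 74.1) had both in 1 library, against 22.2% by independent counts. Differences between the cells of a group could add to this and were not tested.

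Other splits of the same libraries into groups of the same sizes were counted, 100 per contrast with the real one included. For day 14 negative cells against day 0, 1 of 100 splits, the real one, gave as many genes (353, highest other 56). The same held, with 1 of 100, for day 35 negative cells against day 0 (22, highest other 0), day 35 against day 14 negative cells (42, highest other 2), and positive against negative cells at day 14 (137, highest other 55) and day 35 (453, highest other 73). If the libraries are independent, chance is excluded as the cause of these numbers at 1 in 20. The labels do not say whether the replicates came from separate animals, so chance differences between animals are not excluded. For positive cells between the times, 2 of 100 splits gave as many genes (4, highest other 9), and for the interaction also 2 of 100 (7, highest other 12). Both lie under the planned limit of 1 in 20 per contrast, with no correction for the 7 contrasts. In each of these 2 contrasts 1 other split gave more genes than the real one, so chance is not firmly excluded there. For the interaction the splits exchanged the days within each gate. This also removes the change between the times in negative cells, so these splits do not test the interaction alone. The real numbers come from fits of only the groups compared.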
